A study of Danio rerio with 6 samples.

How the data were processed

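Messenger RNA was sequenced from heads of zebrafish (Danio rerio) larvae at 3 days post fertilization, from srrm4[y712] homozygous mutants and their wild-type siblings. There were 6 libraries, 3 per genotype, each labelled replicate 1, 2 or 3. Per the labels' protocols, RNA was isolated with 1 of 2 kits (Qiagen RNeasy mini or Zymo Direct-zol RNA Microprep) and libraries were made with the TruSeq stranded mRNA kit. Which library was made from which RNA kit, the strand setting used in counting and the annotation release are not given in the sources used here. The labels do not say that the replicates came from separate clutches or animals, so the p-values measure the spread between these samples, part of which may be technical.

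The authors deposited raw counts per Ensembl gene for 32520 genes. STAR 2.7.3, featureCounts 1.6.4 from Subread, DESeq2 and the genome build GRCz11 are named in the submitters' processing notes, without the role of each. A second deposited table holds a normalized signal per gene: each column equals the raw counts divided by 1 size factor per library, with values given to 1 decimal, and the largest difference from that quotient was 0.164. The tests ran on the raw counts, and the normalized values entered only 1 alternative test, limma on their log2. Total counts per library ranged from 52510621 to 101032166. No pair of libraries was a duplicate: the chi-square statistic per gene between libraries was at least 4.92.

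Mutant was compared with wild-type in edgeR 4.0.16 (R 4.3.3) with TMM normalization, the filterByExpr filter by genotype, which kept 24765 genes, and the robust quasi-likelihood F test, 2-sided. A Benjamini-Hochberg adjusted p under 0.05 was the threshold. CPM values (counts scaled to library size) were computed with the TMM factors. The design was fixed before the data were examined, with genotype as its only term, and the same fit with the replicate number as a block was written down beforehand beside it. The replicate numbers come from the labels. They were taken as pairs, which the labels do not state: the deviations of same-numbered libraries from their genotype means correlated across genes at 0.863, 0.579 and 0.744 for replicates 1, 2 and 3. Of the unmatched combinations, wild-type replicate 2 with mutant replicate 3 (0.418) and wild-type replicate 3 with mutant replicate 2 (0.365) were also positive, and the other 4 were negative. Deviations within a genotype sum to 0, so the replicate 1 difference alone pushes the values among replicates 2 and 3 above 0. In log2 CPM, wild-type replicate 3 correlated at 0.9959 with mutant replicate 3. Wild-type replicate 2 correlated at 0.9901 with mutant replicate 2 and at 0.9911 with wild-type replicate 3, so the pairing of replicate 2 is the least certain. The blocked value is therefore printed beside each result whose call or count it changed. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were the other tools. The remaining alternatives were other normalization factors, filters on low counts, thresholds, an edgeR fit without robust dispersion and leaving out each library in turn. Fits with the block in DESeq2 and limma-voom, all fits without a pair and the list tests without the genes of the srrm4 chromosome were added after the data had been seen, as was the count of genes without overlap in other splits of the libraries.

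A total of 32 gene lists with 1302 names were also fixed beforehand, and 1281 names matched a gene, 1244 of them by the name in the deposited tables. Lists were tested with camera in limma on log2 CPM (prior count 2), with the preset correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the 32 lists. Camera with an estimated correlation and fry were alternatives. The lists overlap in places, for example her4.1 in the progenitor and the glia lists. The REST list and the glutamatergic and GABAergic list share gria2a, gria2b, grin1a, grin1b, gad1b, gad2 and glra1. The chromosome test was Fisher's exact test, 2-sided. Chromosomes came from RefSeq annotation of the GRCz12tu assembly, used only for names and for which genes lie together, since the counts refer to GRCz11. Of the tested genes, 82.4% had a chromosome (20410 genes). The planned windows in base pairs around srrm4 were not run for lack of GRCz11 coordinates, and distance was counted in genes instead.

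Genes named here are srrm4, its paralog srrm3, the 10 genes with the smallest p (the rule when fewer than 10 pass), up to 4 members of each list with the smallest p, and genes on the srrm4 chromosome past the threshold, of which there were none. Genes called by DESeq2 with the block, genes that differ between replicate 1 and the others, and other genes on that chromosome were named after their values had been seen. Genes that share a name with another (4094) were kept apart by identifier. Figures were drawn with matplotlib.

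The procedure was tested on simulated counts for the 24765 genes, with the means, library sizes and pair structure of the real libraries, the dispersions of the blocked fit, 200 changed genes and a list of 54 further genes shifted by -0.2 on the log2 scale. Of 100 genes changed 1.5-fold and 100 changed 2-fold, edgeR with the block recovered 92% and 100%, and DESeq2 with the block 87% and 99%. The unblocked edgeR fit recovered 0% of each. With the block, 24 of 220 edgeR calls and 27 of 218 DESeq2 calls fell on genes that had been neither changed nor shifted, and 4 and 5 on genes of the shifted list. Camera recovered the shifted list, at an adjusted p of 1.03e-05 without and 2.24e-16 with the block, and called 0 other lists. The simulation drew genes independently, so it does not show how camera behaves when members of a list vary together. Camera with an estimated correlation and fry were not run on the simulated counts, so their power to find a shifted list is not known. With 60 changed genes placed on the srrm4 chromosome, the Fisher test gave an odds ratio of 5.14, against 1.13 with no gene changed.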

Results

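The series measured polyadenylated RNA in heads of 3-day-old zebrafish larvae that were homozygous for the y712 allele of srrm4, and in heads of their wild-type siblings. Srrm4 is a splicing regulator that promotes the inclusion of neural microexons, very short exons used mainly in neurons. The title of the series puts the question of how far srrm4 mutations alter neural development. Each genotype had 3 libraries. Total counts were 75932582, 95887087 and 101032166 in wild-type replicates 1, 2 and 3, and 52510621, 85364733 and 98353600 in mutant replicates 1, 2 and 3. Counts per gene do not show which exons a transcript held, so microexon inclusion was not measured here.

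The replicate number separated the libraries more than the genotype did. The first principal component carried 72.3% of the variance and placed both replicate 1 libraries, wild-type and mutant, apart from the other 4. In total 3388 genes (13.7% of those tested) differed more than 2-fold between replicate 1 and replicates 2 and 3. Genes of hox groups 9 to 13, which pattern the posterior body, were higher in replicate 1 by a median log2 ratio of 2.72, with 16 of 16 genes in that direction. Their summed level was 117.5 CPM in wild-type replicate 1 and 105.7 in mutant replicate 1, and between 14.4 and 21.6 CPM in the other 4 libraries. Ribosomal protein genes were higher in replicate 1 by 1.15 (72 of 72 genes) and skeletal muscle genes by 1.41, while glutamatergic and GABAergic genes stood at -1.08 and photoreceptor genes at -0.93. Both genotypes showed this.

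**Figure D1:**
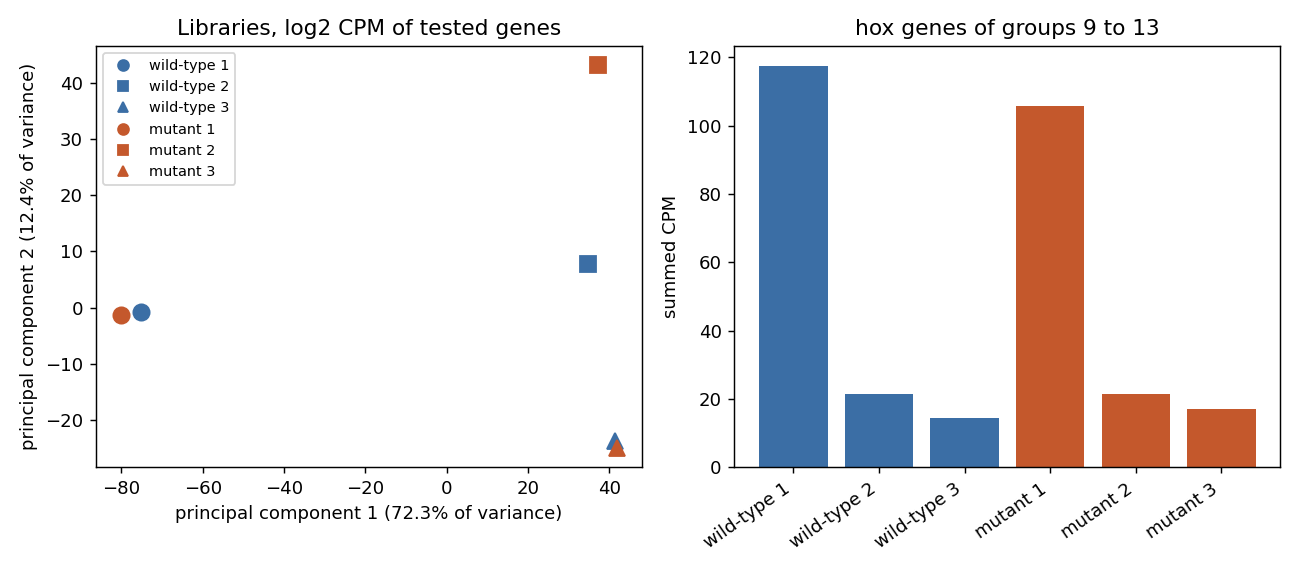
Left, the 6 libraries on the first and second principal components of log2 CPM, with colour for genotype and marker for replicate. Right, bars give the summed CPM of the hox genes of groups 9 to 13 per library. Both replicate 1 libraries lie apart on the first component (72.3% of variance) and hold 117.5 and 105.7 CPM, against at most 21.6 in the other libraries.

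The transcript of the mutated gene was present at similar levels in both genotypes. Srrm4 (ENSDARG00000086327) had 954, 5500 and 6071 counts in wild-type replicates 1, 2 and 3 and 843, 5249 and 6286 in the mutant replicates. The normalized level was 41.1 ± 23.0 CPM in wild-type and 45.1 ± 22.9 CPM in mutant heads (SD, n = 3 each). The log2 fold change was 0.13 (SE 0.62), with a 95% interval of -1.36 to 1.63 and an edgeR adjusted p of 1. With the replicate block it was 0.18 (SE 0.062) with an interval from 0.03 to 0.32, which is a fold of 1.02 to 1.25, at an edgeR adjusted p of 0.939. The mutant library was the higher of its pair for each replicate number, by 0.36, 0.13 and 0.07. Gene-level counts of srrm4 thus give no check of the genotype labels, and a mutation that leaves transcript levels in place would go unseen. Srrm4 also followed the replicate 1 difference, at 14.6 and 18.7 CPM in the replicate 1 libraries and 53.6 to 58.7 CPM in the others.

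The srrm family showed no change in transcript level that passed the test. Srrm3 (ENSDARG00000096920, listed under the clone name si:zfos-375h5.1), the paralog that also acts on neural microexons, measured 9.08 ± 2.64 CPM in wild-type and 9.68 ± 2.26 CPM in mutant heads (SD, n = 3 each). Its log2 fold change was 0.09 (SE 0.28), with an edgeR adjusted p of 1 and a 95% interval of -0.57 to 0.76. With the block that interval ran from -0.10 to 0.30, so a fold change above 1.23 lay outside it. Srrm1 and srrm2, related proteins of the general splicing machinery, had log2 fold changes of 0.05 (SE 0.16) and 0.04 (SE 0.16).

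**Figure D2:**
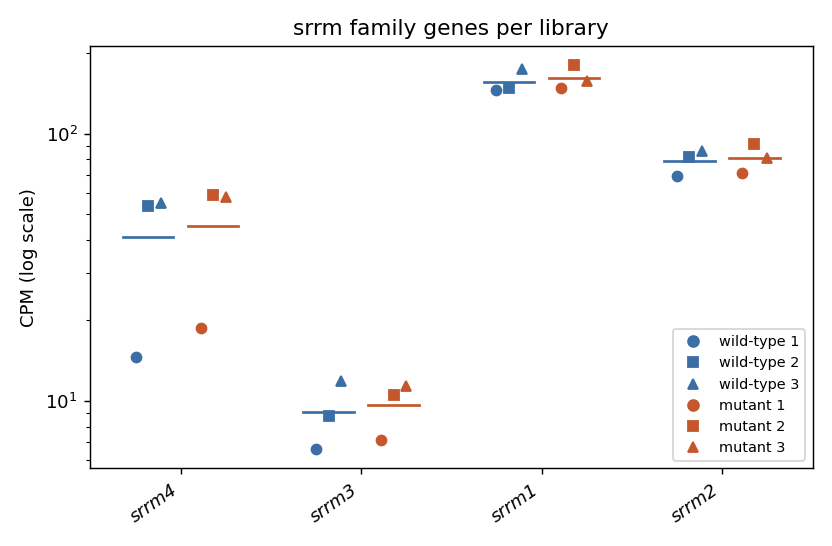
CPM of srrm4, srrm3, srrm1 and srrm2 in each library on a log axis, with blue for wild-type, orange for mutant, markers for replicates and a horizontal line at the mean of the 3 libraries. Srrm4 lies at 14.6 and 18.7 CPM in the replicate 1 libraries and between 53.6 and 58.7 CPM in the other 4.

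The genes that stood out most between mutant and wild-type heads were lower or higher in all 3 pairs, which their choice by p favours. Hspb15 (ENSDARG00000078411), a small heat shock protein, measured 4.92 ± 0.73 CPM in wild-type and 2.23 ± 0.54 in mutant heads, mtmr12 (ENSDARG00000059817), a myotubularin-related protein, 19.1 ± 1.1 and 13.5 ± 0.46, and alkbh2 (ENSDARG00000059856), a DNA repair dioxygenase, 3.33 ± 0.16 and 1.27 ± 0.61 (SD, n = 3 each). Iscub (ENSDARG00000026582), an iron-sulfur cluster scaffold protein, measured 5.59 ± 1.1 CPM in wild-type and 10 ± 1.3 in mutant heads, and the myosin heavy chain myhc4 (ENSDARG00000035438) 12.7 ± 5.9 and 41.8 ± 8.7 CPM (SD, n = 3 each). None of the 24765 genes passed the edgeR test without the block, with 70 genes at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 as well. On simulated data this unblocked edgeR fit found 0% of the genes changed 2-fold, so its count of 0 carries little information. With the replicate block edgeR again called 0 genes, with 1138 (4.6%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.192, and limma-voom 0, while DESeq2 called 17. The blocked edgeR fit left genes with estimates over 2-fold uncalled, among them hspb15, si:ch211-208h16.4 and alkbh2 (edgeR adjusted p 0.192, 0.315 and 0.875), so the recovery seen on simulated data did not carry over to these libraries.

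Of the 17 genes called by DESeq2 with the block, 7 rose and 10 fell in the mutant. In the other splits of the libraries that part all pairs, the same fit called 5, 22 and 1 genes. The count of 17 alone therefore does not set the real split apart. On simulated counts, 27 of 218 calls of this fit fell on genes neither changed nor shifted. That share is above the adjusted p threshold, so some of the 17 may be false calls. The 5 genes whose levels are given above had log2 fold changes in the blocked edgeR fit of -1.15 (SE 0.11) for hspb15, -0.51 (SE 0.064) for mtmr12, -1.44 (SE 0.27) for alkbh2, 0.84 (SE 0.083) for iscub and 1.76 (SE 0.38) for myhc4. DESeq2 with the block gave adjusted p of 1.2e-06, 0.00438, 0.000203 and 1.09e-06 for the first 4, and 0.609 for myhc4. Other genes that fell were si:ch211-208h16.4 (DESeq2 log2 fold change -1.58, SE 0.14, adjusted p 2.5e-23), the lysyl oxidase homolog loxl2b (-0.70, SE 0.094, adjusted p 1.03e-09), si:ch211-283g2.1 (-1.49, SE 0.22, adjusted p 4.31e-08), si:dkey-98f17.3 (-1.02, SE 0.19) and zgc:158463 (-0.84, SE 0.13). The terminal complement component c9 fell by 0.34 (SE 0.076) and the purine nucleoside phosphorylase gene pnp5b by 0.64 (SE 0.15), at DESeq2 adjusted p of 0.0199 and 0.0209. Genes that rose with iscub were the potassium channel gene kcnk5a (0.74, SE 0.16), the actin-severing gelsolin gene gsnb (0.35, SE 0.075), zgc:73226 (0.98, SE 0.21), CU914622.2 (1.97, SE 0.45) and the neighbouring clone-named genes si:ch211-181d7.1 (1.44, SE 0.23) and si:ch211-181d7.3 (1.43, SE 0.26). Reads could be split between those last 2, and between tandem copies of myosin heavy chain genes, so their values are uncertain. Several unblocked edgeR estimates moved when 1 library was left out, which leaves replicate differences unbalanced between the genotypes. Si:ch211-181d7.1 was highest in replicate 2 within each genotype (3.55 CPM in wild-type, 12.5 in mutant). Gsnb was highest in replicate 1 (92.6 and 119.9 CPM). Without mutant replicate 2, si:ch211-181d7.1 fell from 1.67 to 0.22, si:ch211-181d7.3 from 1.49 to 0.22 and kcnk5a from 0.81 to 0.44, and without wild-type replicate 2 the first 2 rose to 2.74 and 2.71 and si:ch211-283g2.1 went from -1.60 to -1.02. Gsnb ranged from 0.07 to 0.61, and zgc:158463 and c9 turned positive without wild-type replicate 1. In DESeq2 with the block, leaving out pair 2 or 3 kept the direction of all 17 genes but called 15 and 7 genes, 11 and 4 of them among the 17. Without the replicate 1 pair it called 9 genes, 7 of them among the 17. The 2 others were myhc4 (log2 fold change 1.26, DESeq2 adjusted p 3.14e-11) and myhz1.3, another fast myosin heavy chain gene (0.87, DESeq2 adjusted p 2.59e-05).

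The remaining genes among the 10 with the smallest p were at low levels and did not pass any of these tests. Si:dkey-34d22.5 measured 0.151 ± 0.036 CPM in wild-type and 0.0203 ± 0.0084 in mutant heads. CR391991.1 measured 0.372 ± 0.016 and 0.737 ± 0.098 CPM, and CR391991.5 measured 0.0815 ± 0.036 and 0.342 ± 0.16 CPM (SD, n = 3 each). Over all tested genes, 505 (2.04%) had all 3 mutant libraries on 1 side of all 3 wild-type libraries, where 10% would be chance for 6 exchangeable libraries. These libraries were not exchangeable, since both replicate 1 libraries stood apart. The 3 other splits that part all 3 pairs gave 502, 545 and 438 genes (2.03%, 2.2% and 1.77%).

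At the preset correlation, the cell division list was shifted up and the photoreceptor list down in the mutant, and neither list passed when the correlation was estimated. The cell cycle and DNA replication list had 33 of 34 members higher in the blocked fit and a median log2 fold change of 0.071, with a camera adjusted p of 0.00126 and 1.01e-05 with the block. With an estimated correlation its camera adjusted p was 0.87, and 0.514 with the block. In the blocked edgeR fit the cyclins ccnb2 (0.19, SE 0.087), ccnb1 (0.16, SE 0.046) and ccne2 (0.14, SE 0.059) and the replicative helicase gene mcm4 (0.14, SE 0.053) did not pass singly after adjustment. The photoreceptor and phototransduction list had 48 of 56 members lower and a median of -0.14, with a camera adjusted p of 0.0294 and 1.29e-07 with the block. With an estimated correlation its camera adjusted p was 0.975, and 0.718 with the block. Rhodopsin (rho, -0.17, SE 0.067), recoverin (rcvrna, -0.17, SE 0.050), the channel gene cnga1 (named cnga1b in the deposited counts, -0.30, SE 0.12) and rom1a (-0.29, SE 0.072) in the blocked edgeR fit did not pass singly after adjustment, and all but rho were lower in each pair. Fry gave an adjusted p of 0.976 for both lists, and 0.357 and 0.525 with the block. The photoreceptor list is also one that separates replicate 1 from the other replicates (-0.93). The cell division list stood at 0.09 there, which is more than its median of 0.071 between the genotypes. In unblocked fits, leaving out wild-type replicate 3 or mutant replicate 1 turned the photoreceptor list upward (camera adjusted p 0.124 and 0.046), and leaving out wild-type replicate 2 gave 0.546. Such fits leave the replicate 1 difference unbalanced between the genotypes. The photoreceptor list was lower in each pair (medians -0.0691, -0.285 and -0.0757). At the preset correlation, with the block and without the replicate 1 pair, it passed (camera adjusted p 8.62e-07). Its unblocked call ended with library totals as the only scaling (camera adjusted p 0.077) and with no filter on low counts (0.204). The unblocked cell division list missed the threshold without wild-type replicate 2 or mutant replicate 1 (camera adjusted p 0.0773 and 0.242), but kept its upward direction in every fit without 1 library. It was higher in each pair (medians 0.0776, 0.0867 and 0.045). At the preset correlation, with the block and without the replicate 1 pair, it passed too (camera adjusted p 0.000962).

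With the replicate block 7 more lists passed at the preset correlation, with small shifts, and none of them passed with an estimated correlation. Genes that the repressor REST silences outside neurons had 39 of 46 members lower (median -0.062, camera adjusted p 0.289, with the block 0.00122, and 0.514 with the block and an estimated correlation). Among them were the neurofilament genes nefla (-0.13, SE 0.076) and nefmb (-0.14, SE 0.040), these and the following gene values being from the blocked edgeR fit. Glutamatergic and GABAergic signalling genes had 40 of 46 members lower (median -0.061, camera adjusted p 0.292, with the block 0.000127, and 0.514 with an estimated correlation), with the vesicular glutamate transporter slc17a7a (-0.22, SE 0.055) and the glutamate receptor grm6b (-0.20, SE 0.046). Inner ear and hair cell genes had 34 of 44 lower (median -0.075, camera adjusted p 0.128, with the block 0.00776, and 0.514 with an estimated correlation), with myo15aa at -0.24 (SE 0.10) and tmc1, a channel protein of hair cells, at 0.49 (SE 0.16). Neural splicing regulators had 33 of 37 members higher (median 0.051, camera adjusted p 0.289, with the block 0.00719, and 0.813 with an estimated correlation), with khdrbs1a at 0.09 (SE 0.034) and nova1 at -0.08 (SE 0.040). Its pair medians were 0.034, 0.086 and -0.029, its blocked call was lost without the replicate 1 pair (camera adjusted p 0.0779), and without wild-type replicate 1 it turned downward past the threshold (0.031). Neural progenitor genes had 22 of 32 higher (median 0.038, camera adjusted p 0.148, with the block 0.0442, and 0.939 with an estimated correlation), with her4.1 at 0.32 (SE 0.10) and sox19a at 0.14 (SE 0.041), but its rise was in pair 2 alone (pair medians -0.011, 0.13 and -0.016). Ribosomal protein genes had 64 of 72 higher (median 0.034, camera adjusted p 0.49, with the block 0.00357, and 0.942 with an estimated correlation), again with a rise in pair 2 alone (pair medians -0.0038, 0.097 and -0.00036). With the block and without the replicate 1 pair the list passed upward (camera adjusted p 0.00123). In unblocked fits it turned downward past the threshold without mutant replicate 1 (camera adjusted p 3.49e-08), wild-type replicate 2 (0.0434) or wild-type replicate 3 (0.00169). Epidermal genes had 25 of 39 higher (median 0.043, camera adjusted p 0.289, with the block 0.0328, and 0.718 with an estimated correlation). Their blocked call ended without the replicate 1 pair (camera adjusted p 0.181), and they turned downward past the threshold without mutant replicate 1 (0.019). The REST list and the glutamatergic and GABAergic list, which share members, were lower in each pair. With the block and without the replicate 1 pair both passed downward (camera adjusted p 0.0403 and 0.0176). In unblocked fits they turned upward past the threshold without mutant replicate 1 (camera adjusted p 0.0106 and 0.000128). The inner ear list was lower in each pair too (medians -0.0592, -0.0541 and -0.0605). With the block and without the replicate 1 pair it passed downward (camera adjusted p 0.0473). Fry with the block called 0 lists (smallest adjusted p 0.157). The correlation estimated with the block was -0.0112 for the REST list, -0.0192 for the glutamatergic and GABAergic list and -0.00296 for the inner ear list. These estimates lie below the preset 0.01, so correlation between members does not account for the lost calls of those lists. The variant with an estimated correlation tests on fewer degrees of freedom, so a lost call there is weak evidence against a shift. No member of any list passed edgeR with the block adjusted over the list alone or over all genes. In replicate 1 against the others, the medians of these 7 lists were -0.75, -1.08, -0.05, -0.58, -0.35, 1.15 and 0.63. The fits without 1 library had no block, so they left this replicate 1 difference unbalanced between the genotypes. Reversals in those fits therefore do not test the blocked shifts.

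**Figure D3:**
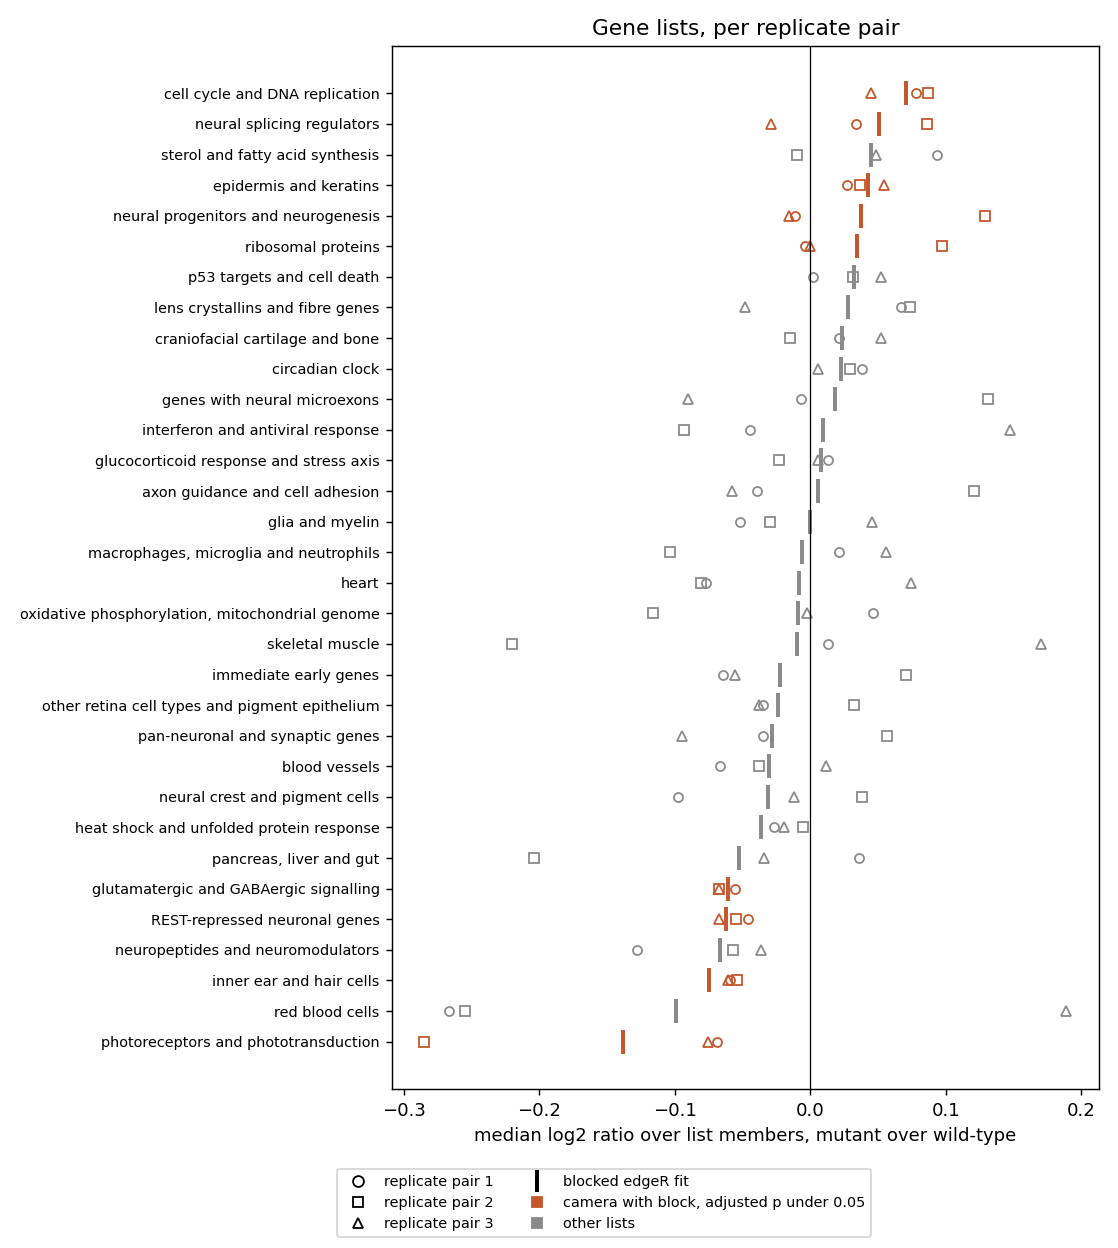
Median log2 ratio of mutant over wild-type for the 32 gene lists, with open markers for the 3 replicate pairs and a vertical tick for the blocked edgeR fit. Orange lists passed camera with the block. The blocked medians ran from -0.14 for photoreceptors to 0.071 for cell division, and several lists had pairs on both sides of 0.

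Genes with neural microexons, the set closest to the known function of Srrm4, showed no shift shared by the pairs (pair medians -0.0067, 0.131 and -0.0901). In the blocked fit 37 of 66 were higher and 29 lower, with a median of 0.018 and a camera adjusted p of 0.391 (0.705 with the block). Examples in that fit were nin (0.18, SE 0.063), cpeb4b (0.15, SE 0.15) and ank3b (-0.10, SE 0.048). Of the other neural lists, the camera adjusted p was 0.791 for pan-neuronal and synaptic genes (29 of 47 lower, median -0.028), 0.148 for neuropeptides (28 of 40 lower, median -0.067), 0.49 for axon guidance and 0.977 for glia and myelin. In the eye and head, it was 0.824 for other retina cells, 0.148 for lens, 0.49 for cartilage and bone, 0.49 for neural crest and pigment cells and 0.382 for blood vessels. For tissues that a head sample can also hold, it was 0.671 for skeletal muscle, 0.791 for heart, 0.148 for red blood cells, 0.789 for macrophages and neutrophils and 0.608 for pancreas, liver and gut. The pancreas, liver and gut list passed without the replicate 1 pair and with the block (camera adjusted p 0.000962); over all 3 pairs its camera adjusted p with the block was 0.0707, and 0.939 with an estimated correlation. Stress and metabolic lists gave 0.789 for interferon response, 0.608 for heat shock and unfolded protein response, 0.354 for p53 targets, 0.789 for immediate early genes, 0.148 for circadian clock genes, 0.789 for glucocorticoid response, 0.24 for sterol and fatty acid synthesis and 0.846 for mitochondrially encoded respiratory genes (camera adjusted p). The block moved none of these 23 lists past the threshold. Median, mean and camera direction differed in sign without the block for skeletal muscle, macrophages, interferon response, glucocorticoid response and glia.

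Genes that differed most between the genotypes lay disproportionately on 1 chromosome, the one that carries srrm4 in the GRCz12tu assembly. It held 12 of the 17 genes called by DESeq2 with the block, namely hspb15, mtmr12, alkbh2, iscub, loxl2b, c9, gsnb, zgc:158463, zgc:73226, si:ch211-208h16.4, si:ch211-283g2.1 and si:dkey-98f17.3, of which 3 rose and 9 fell (Fisher's exact test, odds ratio 40.0, 95% interval 13.1 to 145, p = 5.36e-12). Myhc4, srrm3 and the myosin gene myha (4.14 ± 1.92 CPM in wild-type, 10.1 ± 1.3 in mutant heads, SD, n = 3 each) are on it too. So are several members named above for their lists: ccnb1, rom1a, tmc1, nova1 and sox19a, as well as myhz1.3, so their values cannot be read apart from those of the chromosome. Without the genes of this chromosome 3 lists passed camera at the preset correlation, the inner ear list being added (adjusted p 0.023), and 7 with the block, where the progenitor and epidermal lists missed the threshold (0.072 and 0.0578). An estimated correlation was not run on this set of genes. At an unadjusted edgeR p under 0.01 with the block, 61 of 1175 tested genes on this chromosome (5.19%) were selected, 27 higher and 34 lower in the mutant, against 109 of 19235 on all others (0.567%). The odds ratio was 9.61 with a 95% interval of 6.86 to 13.3 (Fisher's exact test, p = 1.24e-32), and no other chromosome exceeded 1.05%. As edgeR called no gene at its threshold, the planned test on adjusted calls had 0 genes to place. Without the block 8 genes of the 12 at p under 0.01 were on it, and 0 of 19235 tested genes on the others were selected (Fisher's exact test, p = 1.18e-10, lower 95% bound of the odds ratio 28.1). Only 66.7% of the 12 had a known chromosome, so the rest could not be placed. Leaving out pair 1, 2 or 3 left 23, 81 and 40 genes on the chromosome, with odds ratios of 5.89, 5.37 and 5.97.

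**Figure D4:**
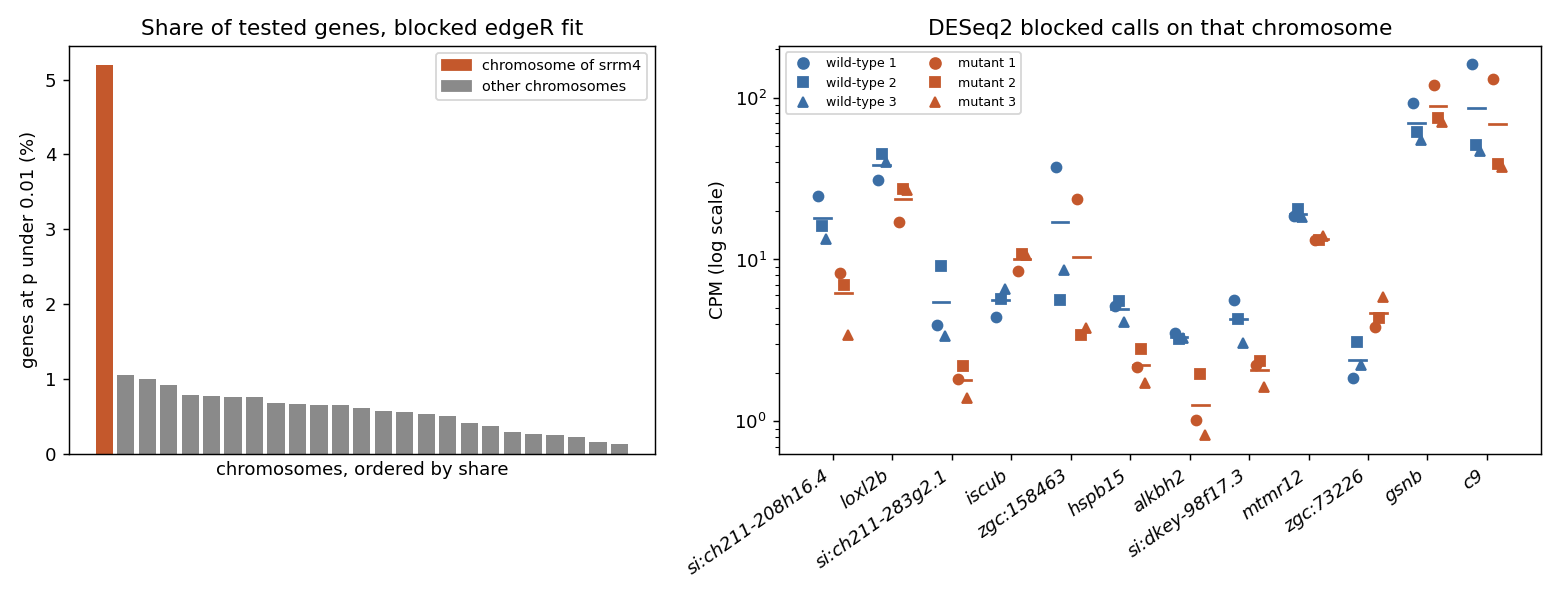
Left, percent of tested genes at an unadjusted p under 0.01 in the blocked edgeR fit for each of 25 chromosomes, ordered by that share, with the chromosome of srrm4 in orange (5.19%, the next 1.05%). Right, CPM per library on a log axis for the 12 genes of that chromosome called by DESeq2 with the block, with blue for wild-type, orange for mutant, markers for replicates and lines at the mean of 3 libraries.

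Distance from srrm4, counted in genes along the chromosome, gave no steady decline. The share at p under 0.01 with the block was 7% (14 of 200 genes, exact 95% interval 3.88 to 11.5) within 100 genes of srrm4, 3.64% (10 of 275, 1.76 to 6.59) from there to 300 genes, 9% (27 of 300, 6.01 to 12.8) up to 600 genes and 2.51% (10 of 399, 1.21 to 4.56) beyond. Si:dkey-98f17.3 lay 32 genes from srrm4, zgc:73226 lay 106 away, and hspb15, iscub, myhc4 and myha lay between 353 and 375 genes away. Hspb15, dab2 and c9 lay side by side at 375, 376 and 377 genes, each at an unadjusted p under 0.01 in the blocked edgeR fit. The intervals here and the Fisher tests on the chromosome treat genes as independent, which neighbouring genes need not be.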

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

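The fits with the block in DESeq2 and limma-voom, camera and fry variants with the block, fits without a pair, the lists without the genes of the srrm4 chromosome and the chromosome counts with the block were chosen after seeing the data; the others had been set before the data were examined. The count of changed genes was 0 in edgeR under every alternative set beforehand, and moved only in DESeq2 with the replicate block (17, and 9, 15 and 7 without pair 1, 2 and 3). For srrm4 the replicate block gave 0.18, and leaving out 1 library gave -0.27 to 0.50; for srrm3 the range was -0.09 to 0.33. Both turned negative without wild-type replicate 1 or mutant replicate 3 (srrm4 -0.267 and -0.086, srrm3 -0.0902 and -0.042), srrm4 also without mutant replicate 2 (-0.10). Both were lower in replicate 1 than in the others (log2 ratio -1.77 for srrm4 and -0.62 for srrm3), so dropping 1 library leaves them unbalanced between genotypes. Whether this accounts for the whole change of srrm3 was not tested. The genes zgc:158463 (-2.24 to 0.53) and c9 (-1.17 to 0.49), both high in replicate 1, were positive only without wild-type replicate 1. Of 437 values recomputed for 21 named genes other than srrm4 and srrm3, 410 kept their direction and side of the threshold, 25 passed the threshold and 2 changed direction. The main fit called no gene, so keeping the side meant staying uncalled. All 25 came from DESeq2 with the block, over all pairs or without the replicate 1 pair. Its 17 calls are among the 21 by choice. Myhc4, called only without the replicate 1 pair, is among them for its small edgeR p. These counts are therefore no measure of stability. Lists past the camera threshold numbered 2, and 9 with the replicate block, 0 with an estimated correlation or fry (0 each with the block too), 1 with library totals as the only scaling, 1 with no filter on low counts, 4 with a CPM of at least 1 in 3 libraries, 5 to 16 when 1 library was left out, 5 without the replicate 1 pair (8 with the block), and 3 without the genes of the srrm4 chromosome (7 with the block). Adjusted p of single lists, with a direction that turned in at least 1 fit without a library, ranged from 3.33e-05 to 0.939 (splicing regulators), 6.26e-06 to 0.862 (REST targets), 2.69e-09 to 0.465 (glutamatergic and GABAergic), 0.000388 to 0.875 (progenitors), 3.54e-11 to 0.546 (photoreceptors), 1.23e-14 to 0.0434 (ribosomal proteins) and 2.99e-05 to 0.694 (epidermis). Those fits had no block and left the replicate 1 difference unbalanced between the genotypes, so they do not test the blocked shifts. Genes on the srrm4 chromosome were 0 at the adjusted threshold, 8 at an unadjusted p under 0.01, 61 with the replicate block, 23, 81 and 40 with it and without pair 1, 2 and 3, and 12 among the DESeq2 calls with the block. The replicate block changed no other call. The windows in base pairs around srrm4 were not run. Depth limits genes such as CR391991.5 and si:dkey-34d22.5, at 0.0815 and 0.151 CPM in wild-type heads.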

Other observations

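All tests of explanations in this part were chosen after the result was seen, except those of a uniform dilution and of other sample splits for the count of changed genes. Hormone and clock genes were among the listed genes with the smallest edgeR p, and none passed after adjustment; log2 fold changes are from the blocked fit. The pituitary hormone precursor gene pomca measured 10.3 CPM in wild-type and 8.27 in mutant heads (log2 fold change -0.31, SE 0.066), and was lower in all 3 pairs, by -0.34, -0.28 and -0.31. Oxytocin (oxt), on the srrm4 chromosome, stood at -0.25 (SE 0.11). Another pituitary hormone gene, tshba, was higher in all 3 pairs (0.31, SE 0.19, by 0.26, 0.46 and 0.18). The clock repressors nr1d4b (0.38, SE 0.099), cry2 (0.14, SE 0.044) and per1b (0.23, SE 0.066) were higher in each pair, while the clock list of 45 genes had 26 higher and 19 lower members. In the lens list, crybb2 (0.72, SE 0.18) and crygn1 (0.46, SE 0.12) were higher in all 3 pairs, at 1.46 and 2.06 CPM in wild-type heads, while the list as a whole had 26 of 48 members higher and 22 lower, with a blocked median of 0.028.

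Some genes of liver, kidney and fast muscle were several-fold higher in both replicate 1 libraries; the examples below were picked after their values had been seen. Over whole lists, 49 of 56 skeletal muscle genes were higher there (median log2 ratio 1.41), but only 10 of 16 pronephros genes (median 0.78) and 29 of 51 pancreas, liver and gut genes (median 0.47, with values down to -2.19). The apolipoprotein gene apoa1a measured 6384 CPM in wild-type replicate 1 and 5507 in mutant replicate 1, and 507 to 671 CPM in the other 4 libraries. The liver fatty acid binding protein gene fabp1b.1 measured 348.5 and 333.8 CPM against 29.0 to 34.8, and the kidney salt transporter gene slc12a3 measured 7.35 and 9.22 CPM against 0.0585 to 0.112. The muscle troponin gene tnni2a.4 measured 2943 and 2684 CPM against 218.1 to 402.6. The forebrain transcription factor gene foxg1a was lower, at 20.5 and 19.2 CPM against 35.1 to 37.0, and so was the GABA synthesis gene gad2, at 54.8 and 53.1 CPM against 195.0 to 208.8.

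The first pattern is that the replicate 1 libraries stood apart in both genotypes. A shift in age alone was argued against by the hox genes of groups 9 to 13, all 16 of which were higher there, the least by 0.435. A uniform dilution of head RNA was argued against by head lists that moved apart by 1.42, with lens genes at 0.49 and photoreceptor genes at -0.93. A candidate explanation is RNA from tissue behind the head in these libraries, which are labelled head like the others: the median ratio of the posterior hox genes was 2.72, against -0.13 for hox groups 1 to 3. The labels name 2 RNA kits without assigning them, and a kit or age difference in addition stays open, as does the source of the uniform shift of ribosomal protein genes.

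The second pattern is the concentration of differing genes on the srrm4 chromosome. A direct effect of srrm4 loss wherever genes lie was argued against as the whole source by the lower bound of the odds ratio, 6.86, and low counts by an odds ratio of 8.04 among genes at 5 CPM or more. Sequence differences linked to the mutated locus, where homozygous mutants and wild-type siblings differ by selection, stay open as a candidate explanation: genes within 100 genes of srrm4 were selected more often than those over 600 away (odds ratio 2.92, interval 1.18 to 7.5), but the share did not fall steadily with distance (7%, 3.64%, 9% and 2.51%), and whether such variants alter expression or only the counting of reads was not tested. Among the 10 splits of the 6 libraries, 4 placed as many genes at p under 0.01 there without the block (real 8, highest other 56), and the split with 56 selected 1395 genes overall and points to the structure of the replicate 1 pair. Of the 4 splits that part all 3 pairs, the real one placed 61 genes on the chromosome with the block and 109 elsewhere, and the highest other 14 and 262, a number of splits too small for a share under 0.05.

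The third pattern is the shift of cell division genes up and of photoreceptor genes down, which passed only at the preset correlation. Less eye tissue in mutant heads remained open: the lens median exceeded the photoreceptor median by only 0.0273 in pair 3, against 0.14 and 0.36 in the other pairs. For slightly younger mutant larvae, the prediction was pan-neuronal genes lower with progenitor genes higher in each pair. It was not met, as 0 of 3 pairs showed this (pan-neuronal medians -0.035, 0.057 and -0.095, progenitor medians -0.011, 0.13 and -0.016 in pairs 1, 2 and 3). These medians were small, so younger larvae were not excluded either. Among the 10 splits, 9 gave as many lists past the threshold (real 2, highest other 20), and among the 4 that part all pairs the block gave 9 lists for the real split and 14, 12 and 3 for the others. For single genes edgeR called 0 in the real split, so the comparison with other splits is void (10 of 10 give as many, highest other 0), and 2 of the 4 pair-parting splits gave as many DESeq2 calls with the block (real 17, highest other 22). For the lists and the DESeq2 calls, the splits are too few for a share under 0.05.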
